A study of Bacillus subtilis with 8 samples.

How the data were processed

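Colonies of Bacillus subtilis 168 were grown on 2xSG plates and taken for RNA after 3 days. Per the labels, RNA was isolated with a column kit and treated with DNase, copied into cDNA with random nonamers and aminoallyl dUTP, coupled to Cy3 or Cy5, and hybridised in pairs on spotted arrays. There were 8 arrays, 4 of rok against wt and 4 of rok-comK against comK, each with 2 arrays per dye orientation. The groups were taken from the labels. The labels give 4 replicates per comparison while the extraction protocol names 3 cultures, so the arrays may not all be independent.

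Each deposited array file lists 8448 spots in 36 grids, with 2 spots for each of 4106 genes and 62 control features. Per the file headers and values, the deposited unit is intensity: foreground and local background brightness per channel, and net intensity after the authors subtracted the background once and then again by grid. The authors left 409 to 417 spots per array without a value, and these were left out. The authors' matrix of the series holds log ratios in the deposited unit ln, read here as the natural logarithm. Their slope on the log2 ratios computed here was 0.692 to 0.816 per array, against 0.693 for a natural logarithm, and they were used only as an alternative, divided by that factor. The channels carry the letters A and B and no dye. A was read as Cy3 and B as Cy5, a reading chosen because the neo marker probe was then brighter in the rok-labelled RNA on all 8 arrays.

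The foreground was corrected with normexp (offset 50) and each array normalised by loess over intensity (span 0.3, control features given no weight) in limma 3.58.1 under R 4.3.3. The 2 spots of a gene were averaged. One limma model over the 8 arrays held a coefficient for each comparison and a common dye coefficient, with 5 residual degrees of freedom, and the difference of the comparisons was tested as a contrast. Genes needed a value on at least 2 arrays of a comparison. Benjamini-Hochberg adjusted p under 0.05 were called, all tests two-sided. The SE is that of the moderated fit (median 0.109, 0.108 and 0.153 for rok against wt, rok-comK against comK and the difference), since the spread of raw ratios includes the dye effect. Confidence intervals are 95% intervals from the same fit. Overlap of calls was tested with Fisher's exact test.

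The model, the tests, 28 gene lists and most alternatives were fixed before the data were examined. Set tests covered 27 lists, all but the genes beside rok, over 3807 genes with values on all arrays: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists. List members were taken from general knowledge of the organism, and sublancin genes also belong to the SPβ list. Genes were matched by locus to a RefSeq annotation that holds names without coordinates (4038 of 4106 matched, 1019 with a newer symbol).

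The rule for named genes, fixed beforehand, takes rok, comK, a few genes of interest, the largest called rises and falls that have 1 sign on all arrays of a comparison, the largest called differences, and up to 4 members of each list by p. It names 201 genes. The text names some of them, a selection made after the values were seen: of 144 genes examined for it, 128 come from the rule and 16 do not. These 16 were chosen after their values were seen, as were further genes named to spell out a small count or an order of genes. A gene counted as above background when its net intensity passed 2.6 robust standard deviations of the local background of the array and channel, a multiple chosen after seeing the data. By it 167, 172, 98 and 86 genes were not above background on any array in rok, wt, rok-comK and comK. Spots ranged up to 65240, and those over 40000 may understate a fold change.

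The pipeline was tested on simulated data, with known changes of log2 0.5, 1 and 2 in 67, 67 and 66 of 3807 genes in each comparison (131, 132 and 128 in the difference) and none in the others. It called 77.6%, 92.5% and 100% of changed genes in rok against wt, 67.2%, 100% and 100% in rok-comK against comK, and 42.7%, 88.6% and 100% in the difference. False calls made up 9.1%, 7.3% and 5.6% of calls. A shifted list was called, and so was 1 of 26 other lists. The simulated noise was independent between genes and arrays and of equal spread in both comparisons. These rates therefore do not cover genes that vary together or arrays that share a culture.

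Alternatives concerned background correction, offset, normalisation, scaling between arrays, dye term, separate fits, moderation, handling of duplicate spots, threshold, set test, a replicate block, a filter on dim genes, the authors' values, and leaving out each array. Most changed 1 choice, but separate fits drop both the pooled spread and the common dye coefficient, and the authors' values differ in background correction and normalisation. Filters on genes never above background and on spots over 40000 were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.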

Results

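Transcript levels were measured in colonies of Bacillus subtilis 168 grown on plates to day 3, on spotted DNA arrays read with the dyes Cy3 and Cy5. The title of the series gives its subject as the part Rok plays in the structure of the biofilm. Rok is a DNA-binding repressor, and one of its known targets is comK, the gene of the master activator of competence (the state in which cells take up DNA). A strain labelled rok was hybridised directly against the wild type (wt) on 4 arrays, and a strain labelled rok-comK against one labelled comK on 4 others, each with 2 arrays per dye orientation. Each slide held 2 spots for each of 4106 genes, and 3964 to 4018 genes had a value on a given array. Median background-subtracted intensity per array and dye ran from 754 to 5490, the lowest in Cy3 on rok against wt replicate 1. Of the genes measured, 3932 were above background on at least 1 array in the rok strain, 3927 in wt, 3964 in rok-comK and 3976 in comK. The number of arrays limits the precision. The series states 4 biological replicates while the extraction protocol speaks of 3 cultures, so some arrays may share a culture. Fold changes are given as log2, labelled rok strain over its reference, with the standard error (SE) of the fit and n = 4 arrays unless stated.

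The probe of rok itself was brighter in the strains that carry the rok label. It (BSU14240) was higher in the strain labelled rok than in wt (log2 2.59, SE 0.109, adjusted p = 3.01e-08, higher on 4 of 4 arrays) and in rok-comK than in comK (log2 2.12, SE 0.109, adjusted p = 2.4e-06, 4 of 4 arrays). A probe for the neomycin resistance marker neo was brighter in the RNA read as rok-labelled on all 8 arrays, by 5.57 log2 units (SD 0.52, n = 4) in rok and 6.17 (SD 0.94, n = 4) in rok-comK, and the direction of every comparison rests on it, since the dyes of the channels were read from this probe. These sizes are uncertain, as its median net intensity was 54288 in rok and 50418 in rok-comK, over the mark of 40000, and in wt it was above background on 3 of 4 arrays. Among the 10 genes beside rok, mobA (molybdopterin cofactor synthesis) rose by 0.51 and moeB by 0.53 in rok against wt, ykuS fell by 0.39, and moeB rose by 0.55 in rok-comK against comK. None of these 4 calls held on leaving out each array in turn. The call of mobA ended without 2 arrays (rok against wt replicates 2 and 3, adjusted p up to 0.0972), that of ykuS without 2 (replicates 1 and 3, up to 0.0655). The calls of moeB ended without 6 (all but rok against wt replicates 1 and 4, up to 0.197) and 4 arrays (the rok-comK arrays, up to 0.269).

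The first comparison asks what differs between the strain labelled rok and wt. The genes for DNA uptake rose most. In the list of late competence genes, which act in DNA binding, uptake and recombination, 27 of 32 members rose and none fell (30 rose when adjusted over the list alone), with a median log2 change of 2.59 (1.05 with genes that have a spot over 40000 left out). In the comG operon, which encodes the pseudopilus that draws DNA to the cell, comGF rose by 5.23 (SE 0.29, adjusted p = 3.12e-07), a 37.6-fold change, and comGA, the ATPase of that system, by 4.81 (SE 0.23). The helicase-like uptake protein gene comFA rose by 4.11 (SE 0.096) and the nuclease gene nucA by 4.09 (SE 0.164). Another member of the list, dprA, rose by 3.16 (SE 0.103). All 5 were higher on 4 of 4 arrays. Their activator gene comK rose 3.16-fold (log2 1.66, SE 0.132, adjusted p = 7.98e-06, 4 of 4 arrays). The set test called the late competence list up with the preset correlation (adjusted p = 2.78e-37) and with an estimated correlation (adjusted p = 0.0058). In the list of competence and global regulators 1 of 20 members rose (1 adjusted over the list alone), the sensor kinase gene degS, by 0.53. Its call ended without rok against wt replicate 2 (0.53, adjusted p = 0.0534), and the list was not called (adjusted p = 0.642).

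**Figure D1:**
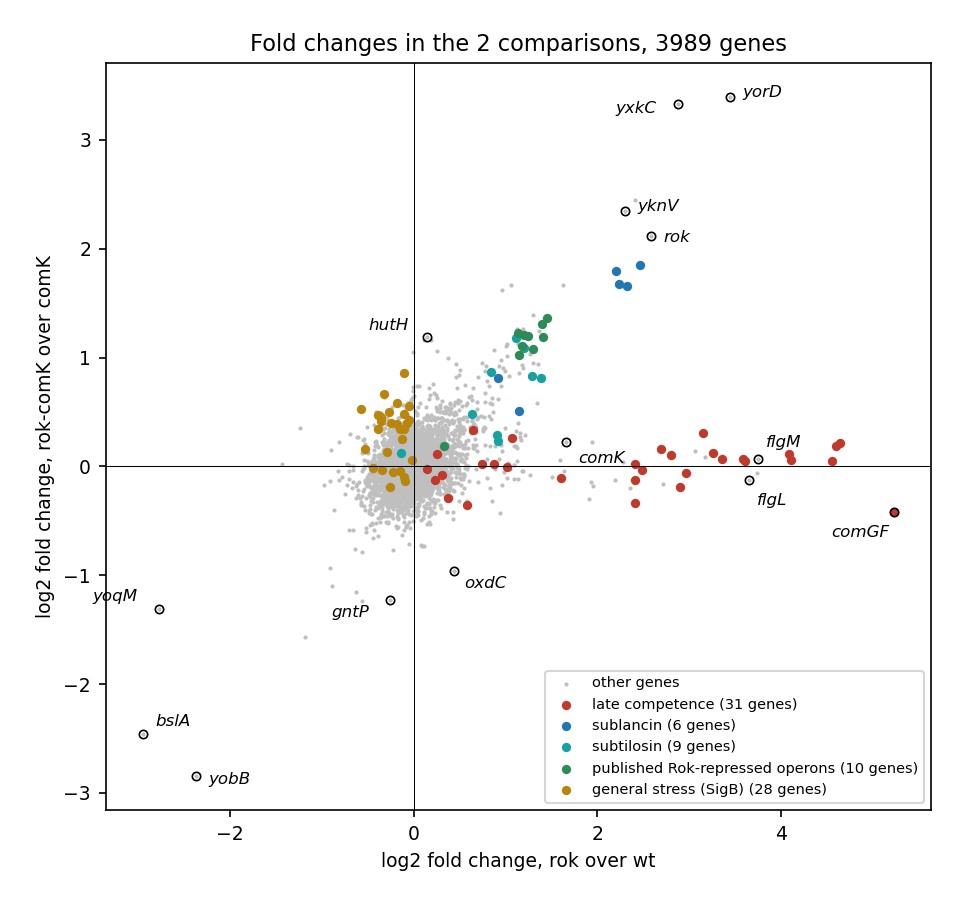
Log2 fold change of each of 3989 genes in rok over wt (horizontal) and in rok-comK over comK (vertical), with 5 gene lists coloured and single genes circled. Late competence genes spread along the horizontal axis up to comGF at 5.23, while sublancin, subtilosin and the operons known as Rok targets lie above 0 on both axes, but for 1 subtilosin gene.

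A run of flagellar genes rose in rok against wt as well. Of 48 tested members of the motility and chemotaxis list 8 rose and none fell (8 adjusted over the list alone). The gene of the anti-sigma factor FlgM rose by 3.75 (SE 0.129, adjusted p = 8.97e-09), the hook-junction genes flgL by 3.65 (SE 0.117) and flgK by 3.17 (SE 0.08), and fliW by 1.91 (SE 0.104), and these lie beside the comF operon in the gene order. The flagellin gene hag had a log2 change of -0.63 (SE 0.212, adjusted p = 0.0791), which did not pass. The median of the list was -0.03, its mean 0.25, and camera did not call it (adjusted p = 0.315), while fry called it up (adjusted p = 0.0274).

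**Figure D2:**
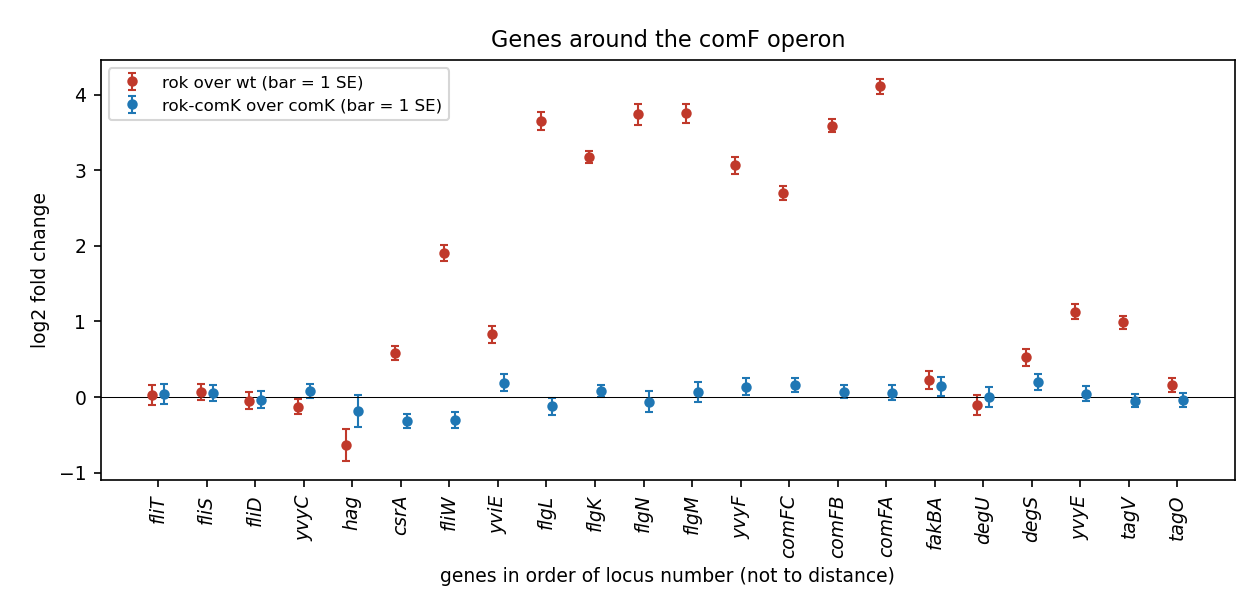
Log2 fold change of the genes around the comF operon in order of locus number, not of distance, in both comparisons, with bars of 1 SE from the fit. From comFA at 4.11 to flgL at 3.65 the rok over wt values lie above 2.5, and the rok-comK over comK values of these genes lie between -0.12 and 0.16.

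Among the genes of the biofilm matrix, bslA, which encodes the water-repellent surface protein of the biofilm, fell 7.72-fold in rok against wt (log2 -2.95, SE 0.151, adjusted p = 1.59e-07, lower on 4 of 4 arrays). The signal peptidase gene sipW rose by 0.64 (SE 0.164, adjusted p = 0.0275), a call that ended without 3 arrays (rok against wt replicates 1, 3 and 4, adjusted p up to 0.0798). The fibre gene tasA (0.04, SE 0.122, adjusted p = 0.877) and its partner tapA (0.65, SE 0.194, adjusted p = 0.0511) did not pass. In the matrix protein list 1 of 4 members rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.34, a mean of -0.41 and no call (adjusted p = 0.939). None of the 15 genes of the eps operon for exopolysaccharide passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (0 each), and its first gene epsA changed by 0.08 (95% interval -0.11 to 0.26). Of the 5 genes for poly-gamma-glutamate none passed, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05), and neither list was called (adjusted p = 0.939 and 0.603).

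The sublancin genes and most subtilosin genes rose in rok against wt. All 6 sublancin genes rose (6 adjusted over the list alone), among them the glycosyltransferase gene sunS by 2.47 (SE 0.15) and the peptide gene sunA by 1.15 (SE 0.118, adjusted p = 6.39e-05). Of the 9 subtilosin genes 8 rose (8 adjusted over the list alone), with albD at 1.39 (SE 0.093). In a pair of operons recalled from published work on Rok, 9 of 10 genes rose (9 adjusted over the list alone), among them yybJ by 1.2 (SE 0.102) and liaL (yydI on the array) by 1.46 (SE 0.114). These 3 lists were called up (adjusted p = 3.14e-10, 1.29e-08 and 4.15e-12), and with an estimated correlation none was (adjusted p = 0.088 for each). In the list of other peptide and polyketide antibiotics 10 of 32 rose and 6 fell (14 and 6 adjusted over the list alone). The risen genes included ppsA and ppsE of plipastatin synthesis (0.95 and 1.14), and the fallen ones were the bacilysin genes, such as bacD (ywfE) at -0.91 (SE 0.136) and bacC (ywfD) at -0.89 (SE 0.138). That list was called up (adjusted p = 0.047, and 0.789 with an estimated correlation), a call lost without replicate 3 (median 0.07, adjusted p = 0.696). Of 12 cannibalism toxin genes, which kill sibling cells, 3 rose (3 adjusted over the list alone): sdpB by 1 (SE 0.115), sdpA by 0.77 (SE 0.098) and sdpR by 0.47. The call of sdpR ended without 3 arrays (rok against wt replicates 1, 2 and 3, adjusted p up to 0.0982). The toxin peptide gene of this operon, spbC (yvaY), had a log2 change of 0.25 (adjusted p = 0.189). The list was called up (adjusted p = 0.0479, and 0.789 with an estimated correlation), a call that ended without rok against wt replicate 2 or 3 or rok-comK against comK replicate 3 (medians 0.07, -0.04 and 0.12).

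Genes of the SPβ prophage and of ICEBs1 were among those that rose in rok against wt. In the SPβ prophage, which carries the sublancin genes, 42 of 175 tested genes rose and 3 fell (46 and 3 adjusted over the list alone). The gene yorD rose 10.9-fold (log2 3.44, SE 0.121, adjusted p = 8.97e-09), while yoqM fell 6.83-fold (log2 -2.77, SE 0.129), yoqL by 1.18 and yoqJ by 0.64. In the conjugative element ICEBs1 9 of 24 rose and 1 fell (13 and 1 adjusted over the list alone), with yddK at 1.04 (SE 0.104), the regulator rapI at 0.83 (SE 0.115), and the fall in ydcL (-0.59, SE 0.101). Both lists were called up (adjusted p = 5.36e-07 and 0.000142), with adjusted p = 0.263 and 0.388 with an estimated correlation. In the PBSX prophage 3 of 33 rose (1 adjusted over the list alone): xkdU by 0.49 (SE 0.094), and xkdK and xkdH, whose calls each ended without any 1 of the 8 arrays (adjusted p up to 0.137 and 0.153). In the skin element 2 of 47 rose, yqaP by 1.35 and rttG (yqcG) by 0.58, and phrE fell by 0.58 (2 and 1 adjusted over the list alone). Neither the PBSX nor the skin list was called (adjusted p = 0.0689 and 0.939).

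Some spore genes fell in rok against wt. In the forespore list 9 of 35 genes fell and none rose (10 adjusted over the list alone), all 9 of them for small acid-soluble spore proteins, with sspK at -0.81 (SE 0.142) and sspJ at -0.98 (SE 0.208). The call of sspJ ended without replicate 3 (-0.86, adjusted p = 0.0565). In the mother cell list 5 of 29 fell (5 adjusted over the list alone): spoIIIAA by 0.4, spoVM by 0.44, spoIVFA by 0.36, spoVD by 0.43 and spmB by 0.33. Their calls ended without 1 array (rok against wt replicate 2), 2 arrays (replicates 2 and 3), 7 arrays (all but rok against wt replicate 1), 5 arrays (rok against wt replicates 1 and 4, rok-comK against comK replicates 2, 3 and 4) and 7 arrays (all but rok against wt replicate 1), with adjusted p up to 0.0576, 0.103, 0.0974, 0.117 and 0.157. Both lists were called down (adjusted p = 0.000142 and 8.49e-06), with adjusted p = 0.789 and 0.743 with an estimated correlation, and the forespore call was lost without replicate 3 (median -0.05, adjusted p = 0.145). In early sporulation 3 of 14 fell (3 adjusted over the list alone), racA by 0.4, spoIIR by 0.45 and spoIIQ by 0.35. The calls of these genes ended without 2 arrays (rok against wt replicates 1 and 2), 2 arrays (replicates 2 and 3) and 4 arrays (rok against wt replicates 2, 3 and 4, rok-comK against comK replicate 4), with adjusted p up to 0.065, 0.128 and 0.146. In the coat list 1 of 42 fell (0 adjusted over the list alone), cotM by 0.7, a call that ended without replicate 2 (-0.71, adjusted p = 0.084). Neither the early nor the coat list was called (adjusted p = 0.377 and 0.0921). On replicate 1 of rok against wt the median of the mother cell list was 0.23, against -0.39 to -0.31 on the other 3 arrays. The ribosomal RNA probes of that array together gave a log2 ratio of -1.2, against -0.09 to 0.4 on those 3.

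In metabolism and stress, all 4 genes of the nitrate reductase operon rose in rok against wt, narH by 1.09 (SE 0.119, adjusted p = 9.98e-05), narG by 0.97, narJ by 0.8 and narI by 0.55. They were the 4 that rose of 20 in the anaerobic list (4 adjusted over the list alone), which was not called (adjusted p = 0.0689). In the general stress list 4 of 28 fell (4 adjusted over the list alone): ohrB (ykzA) by 0.58, csbA by 0.53, ctc by 0.44 and rsbW by 0.35. These calls ended without 3 arrays (rok against wt replicates 1, 2 and 3), 2 arrays (replicates 2 and 3), 1 array (replicate 2) and 7 arrays (all but rok against wt replicate 1), with adjusted p up to 0.123, 0.0968, 0.0982 and 0.0897. The arginine genes carA and carB rose by 0.66 and 0.48, the 2 of 9 in their list (7 adjusted over the list alone), and the call of carB ended without 2 arrays (rok against wt replicates 2 and 3, adjusted p up to 0.15). Of 14 purine genes purE rose (0 adjusted over the list alone), by 0.6, a call that ended without 4 arrays (rok against wt replicates 1, 2 and 4, rok-comK against comK replicate 2, adjusted p up to 0.129). The general stress list was called down (adjusted p = 0.000142), and the arginine and purine lists up (0.000995 and 0.0423), with adjusted p = 0.743, 0.743 and 0.789 with an estimated correlation, and the purine call was lost without replicate 2 or 3 (adjusted p = 0.18 and 0.145). The tricarboxylic acid cycle gene sucD rose by 1.1 (SE 0.151), 1 of 12 in its list (1 adjusted over the list alone). The xylanase gene xynA rose by 0.79 (SE 0.137), 1 of 16 secreted enzymes (1 adjusted over the list alone). The iron uptake gene feuA rose by 0.4, 1 of 11 (1 adjusted over the list alone), a call that ended without 5 arrays (rok against wt replicates 1 to 4, rok-comK against comK replicate 2, adjusted p up to 0.0841). Among 54 ribosomal protein genes rpsR rose by 0.41 and rpmEA, rpmA and rpmEB fell by 0.71, 0.44 and 0.41 (0 and 1 adjusted over the list alone), of which only rpmEA kept its call on leaving out each array. For rpsR the call ended without 7 arrays (all but rok against wt replicate 1), for rpmA without 7 (all but rok against wt replicate 3) and for rpmEB without 6 (all but rok against wt replicate 4 and rok-comK against comK replicate 1), with adjusted p up to 0.149, 0.166 and 0.125. These last 4 lists were not called (adjusted p = 0.109, 0.939, 0.939 and 0.186).

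**Figure D3:**
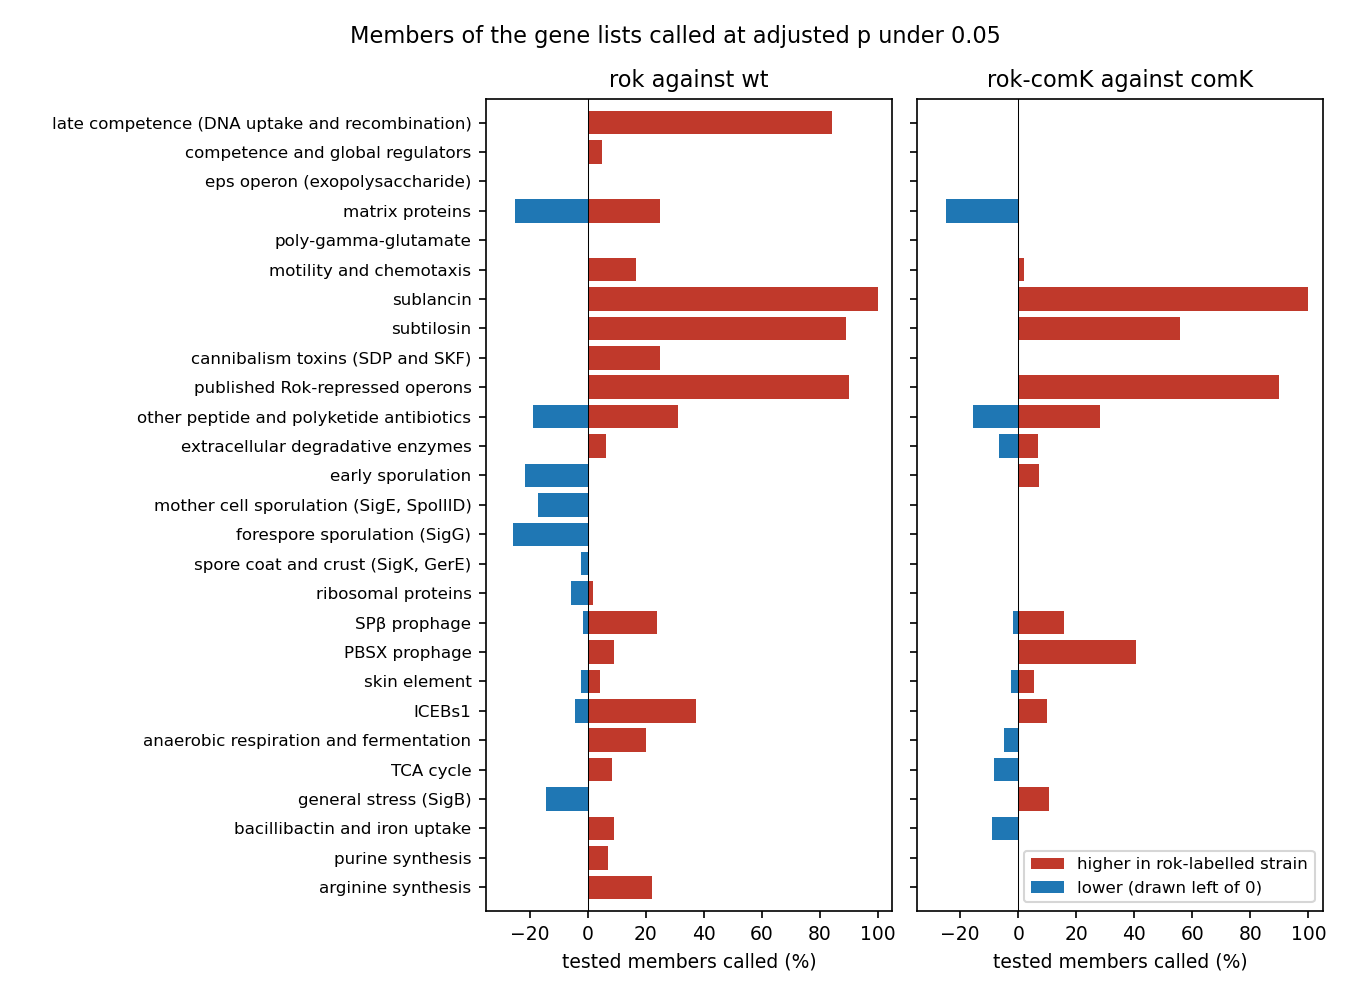
Share of the tested members of each gene list, in percent, that were called higher (right of 0) or lower (left of 0) in each comparison at an adjusted p under 0.05. The late competence list has 27 of 32 members called in rok against wt and 0 of 31 in rok-comK against comK, and the sublancin list has 6 of 6 in both.

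Over all genes, 518 of 4068 tested passed in rok against wt, 348 higher and 170 lower, and 111 of them changed at least 2-fold (106 higher, 5 lower). The 5 that fell at least 2-fold were bslA, yoqM, yobB, pghL (yndL) and yoqL. The gene yobB was not above background in the rok strain, so it was at least 3.57-fold lower there. The gene pghL fell by 1.44, a call lost without replicate 3 (-1.22, adjusted p = 0.0581). The set test called 13 of 27 lists (10 up, 3 down), and with an estimated correlation 1, late competence. The count fell to 240 without a dye coefficient (199 higher, 41 lower), to 280 without replicate 2 (223 and 57) and to 363 under median centring (273 and 90). It was 186 (166 and 20) when the 4 arrays were fitted on their own, where neither the spread nor the dye coefficient is shared, and 487 (324 and 163) with a dye coefficient per comparison in the shared fit.

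The second comparison asks what the strain labelled rok-comK shows against comK. Sublancin genes, some subtilosin genes and most genes of the published Rok-repressed operons rose here too, and the late competence genes did not pass. All 6 sublancin genes rose (6 adjusted over the list alone), sunS by 1.85 (SE 0.15, adjusted p = 4.77e-05) and sunA by 0.51 (SE 0.118, adjusted p = 0.034). The call of sunA ended without any 1 of the 4 rok-comK arrays (0.45 to 0.58, adjusted p up to 0.246). Of 9 subtilosin genes 5 rose (7 adjusted over the list alone), albE by 1.18 (SE 0.1), albF by 1.09 (SE 0.096), albG, albC and albD. Of the published Rok-repressed operons 9 of 10 rose (9 adjusted over the list alone), with liaM (yydJ) at 1.23 (SE 0.099) and yybJ at 1.21 (SE 0.102). In the list of other antibiotics 9 of 32 members rose and 5 fell (13 and 5 adjusted over the list alone). Among the risen were ppsA and ppsB of plipastatin synthesis, by 0.97 and 1.07. The 5 fallen were bacilysin genes, bacA (ywfB) by 1.15 (SE 0.129), bacC by 1.1, bacB, bacD and bacF, and bacE was not among them. These 4 lists were called up (adjusted p = 1.15e-11, 2.37e-09, 2.5e-16 and 0.00125), and with an estimated correlation none was (adjusted p = 0.0757, 0.0757, 0.0757 and 0.705). None of the 12 cannibalism toxin genes passed in limma over all genes (1 adjusted over the list alone, 2 at an unadjusted p under 0.05), and the list was not called (adjusted p = 0.168).

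In the late competence list 0 of 31 tested genes passed in limma, over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05), with a median of 0.02, and the list was not called by camera (adjusted p = 0.975) or fry (adjusted p = 0.96). The uptake gene comFA changed by 0.06 (95% interval -0.15 to 0.27) and nucA by 0.11 (-0.25 to 0.47), and comGA had no value on these arrays. The comK probe, above background on 4 of 4 arrays in both strains with the comK label, changed by 0.23 (SE 0.132, adjusted p = 0.365). In the motility list 1 of 48 rose (1 adjusted over the list alone), flgB by 0.58. Its call ended without 3 arrays (rok-comK against comK replicates 1, 2 and 4, adjusted p up to 0.151), and the list was not called (adjusted p = 0.523). The surface protein gene bslA fell 5.51-fold (log2 -2.46, SE 0.151, adjusted p = 5.17e-06, lower on 4 of 4 arrays), the 1 of 4 matrix protein genes to pass (1 adjusted over the list alone). The fibre gene tasA changed by 0.15 (adjusted p = 0.537) and epsA by -0.09 (-0.27 to 0.1). Of 15 eps genes, 4 tested poly-gamma-glutamate genes and 20 regulators none passed in limma, over all genes or adjusted over the list alone (0, 0 and 3 at an unadjusted p under 0.05). The matrix protein, eps, poly-gamma-glutamate and regulator lists were not called (adjusted p = 0.946, 0.786, 0.975 and 0.616).

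**Figure D4:**
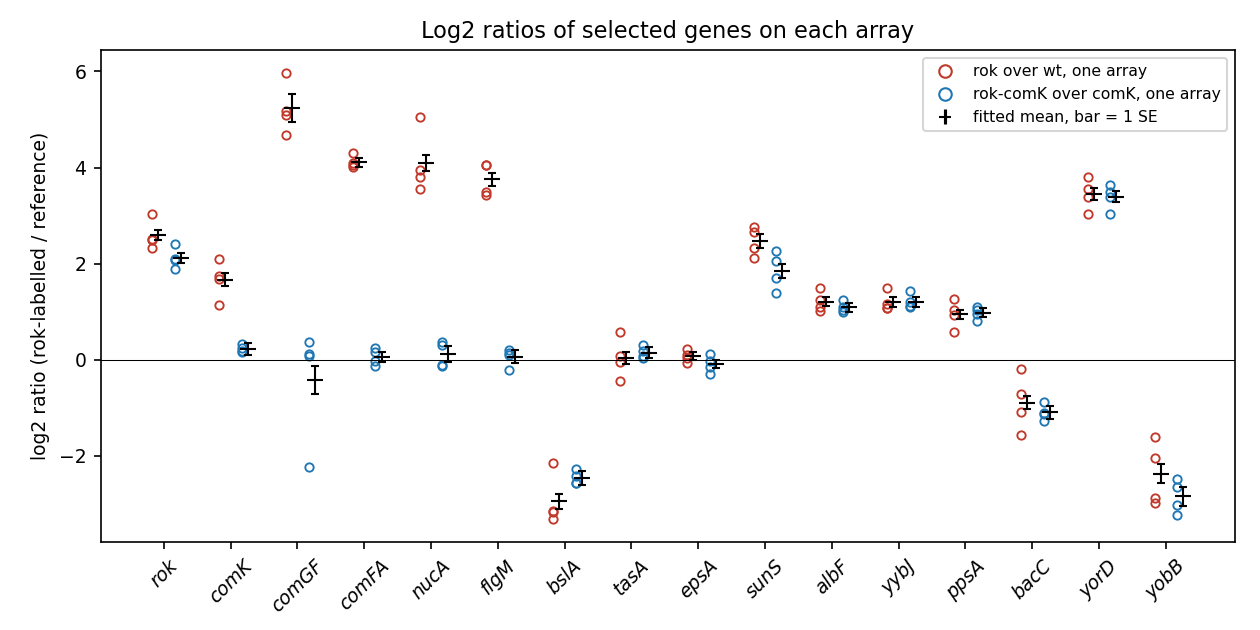
Log2 ratio of the rok-labelled strain over its reference on each array (circles, n = 4 arrays per comparison where all have a value) for selected genes, with the fitted mean and a bar of 1 SE. bslA lies below -2 on all 8 arrays and yorD above 3, while comFA lies near 4 in rok over wt and near 0 in rok-comK over comK.

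Genes of the SPβ and PBSX prophages rose in rok-comK against comK. In SPβ 25 of 159 tested genes rose and 3 fell (35 and 3 adjusted over the list alone), with yorD up 10.5-fold (log2 3.39, SE 0.121, adjusted p = 1.14e-07), yoqL down by 1.57, yoqM by 1.31 and yoqJ by 0.76. The call of yoqJ ended without 3 arrays (rok-comK against comK replicates 2, 3 and 4, adjusted p up to 0.0706). In PBSX 13 of 32 rose and none fell (20 adjusted over the list alone), with xkdU at 0.84 (SE 0.094) and xkdX at 0.55 (SE 0.1). The call of xkdX ended without 3 arrays (rok-comK against comK replicates 2, 3 and 4, adjusted p up to 0.0961). Of 20 tested ICEBs1 genes yddK rose by 0.83 and rapI by 0.58 (2 adjusted over the list alone), and the call of rapI ended without 3 arrays (rok-comK against comK replicates 1, 2 and 3, adjusted p up to 0.144). The 3 lists were called up (adjusted p = 2.41e-16, 2.74e-13 and 0.0374), with adjusted p = 0.0757, 0.204 and 0.689 with an estimated correlation. The ICEBs1 call ended without rok-comK against comK replicate 1, 2 or 3 (medians 0.18 to 0.23, adjusted p up to 0.0743). In the skin element yqaP rose by 0.94 and rttG by 0.45 and yqcC fell by 0.43, of 38 tested (2 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.113). The calls of rttG and yqcC ended without 5 arrays (rok against wt replicate 2 and the 4 rok-comK arrays) and 3 arrays (rok-comK against comK replicates 2, 3 and 4), with adjusted p up to 0.253 and 0.149.

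The other lists showed few calls in rok-comK against comK. In general stress 3 of 28 rose (14 adjusted over the list alone): ydaD by 0.86 (SE 0.124), lyxE (ydaE) by 0.58 and ydaG by 0.5, and the list was called up (adjusted p = 1.41e-05, and 0.689 with an estimated correlation). The calls of lyxE and ydaG ended without 3 arrays (rok-comK against comK replicates 2, 3 and 4) and 4 arrays (these and rok against wt replicate 2), with adjusted p up to 0.149 and 0.261. The siderophore gene dhbB fell by 0.72, 1 of 11 in the iron list (5 adjusted over the list alone). The regulator gene arfM of the anaerobic list fell by 0.52, 1 of 20 (1 adjusted over the list alone), and fumC (citG) of the tricarboxylic acid cycle by 0.52, 1 of 12 (1 adjusted over the list alone). Among secreted enzymes xynA rose by 0.92 and amyE fell by 0.47, of 15 (1 and 1 adjusted over the list alone), and of 14 early sporulation genes kinB rose by 0.37 (1 and 1 adjusted over the list alone). The calls of dhbB and fumC ended without each of the 4 rok-comK arrays (adjusted p up to 0.237 and 0.213). Those of arfM and kinB ended without these or rok against wt replicate 2 (up to 0.247 and 0.255), and that of amyE without 4 arrays (rok against wt replicate 2, rok-comK against comK replicates 2, 3 and 4, up to 0.219). None passed in limma, over all genes or adjusted over the list alone, of 29 mother cell, 35 forespore, 42 coat, 54 ribosomal, 14 purine or 9 arginine genes (2, 0, 2, 7, 5 and 6 at an unadjusted p under 0.05). The iron, anaerobic and mother cell lists were called down (adjusted p = 0.00104, 0.0424 and 0.0374) and the purine and arginine lists up (0.0115 and 0.00047), with adjusted p = 0.689, 0.723, 0.843, 0.689 and 0.689 with an estimated correlation. The mother cell call ended without replicate 1 or 4 (medians -0.07 and -0.06), and the anaerobic and purine calls without replicate 2 or 4 (medians -0.04 and -0.06, 0.16 and 0.12) of rok-comK against comK. The tricarboxylic acid cycle, secreted enzyme, early sporulation, forespore, coat and ribosomal lists were not called (adjusted p = 0.5, 0.5, 0.738, 0.679, 0.15 and 0.946).

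Over all genes, 237 of 4010 tested passed in rok-comK against comK, 153 higher and 84 lower, and 47 changed at least 2-fold (39 higher, 8 lower). The largest rises beside yorD were yxkC by 3.32 (SE 0.186), yjcM by 2.45 (SE 0.13) and yknV by 2.34 (SE 0.131), and the largest fall was yobB, 7.18-fold (log2 -2.84, SE 0.199). The set test called 13 of 27 lists (10 up, 3 down), and with an estimated correlation 0 (5 at an unadjusted p under 0.05, and 5 by fry after adjustment). The count was 82 (70 higher, 12 lower), 96 (82 and 14) and 90 (77 and 13) without rok-comK against comK replicates 2, 3 and 4, and 444 (245 and 199) with the arrays scaled to 1 spread. It was 663 (378 and 285) when these 4 arrays were fitted on their own, 183 (127 and 56) with a dye coefficient per comparison in the shared fit, and 331 (202 and 129) without replicate 1 of rok against wt.

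The direct test of the difference asks which effects of the rok label differ between the 2 comparisons. Late competence genes differed most: 23 of 31 were higher in rok against wt than in rok-comK against comK, and none lower (27 adjusted over the list alone), with a median difference of 2.54 (0.986 with genes that have a spot over 40000 left out). Of the pseudopilus genes, comGF differed by 5.65 (SE 0.41, adjusted p = 5.92e-06), though on rok-comK against comK replicate 4 its ratio was -2.22 against 0.08 to 0.38 on the others. The gene comFA differed by 4.05 (SE 0.136, adjusted p = 5.3e-08), and comK differed by 1.44 (SE 0.186). Both strains of rok-comK against comK carry the comK label, so what the comK probe reads in them stays open. The list was called (adjusted p = 3.95e-49, and 0.00292 with an estimated correlation). Of 48 motility genes 5 differed (5 adjusted over the list alone), flgM by 3.69, flgL by 3.78, flgK by 3.09, fliW by 2.21 and csrA by 0.9, and the list was not called (adjusted p = 0.584).

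The peptide and matrix genes gave few called differences. The matrix gene bslA differed by -0.49 (95% interval -0.96 to -0.02, adjusted p = 0.307), and passed without rok against wt replicate 3 (-0.74, adjusted p = 0.0177). The prophage gene yorD differed by 0.05 (-0.33 to 0.43), though with the arrays scaled to 1 spread it was lower in rok against wt (-0.81, adjusted p = 0.0254), and yybJ by 0 (-0.32 to 0.31). None of 6 sublancin genes passed in limma (4 adjusted over the list alone, 4 at an unadjusted p under 0.05), and the list was called higher in rok against wt (median 0.59, adjusted p = 0.00465, and 0.812 with an estimated correlation). Of 9 subtilosin genes albD differed by 0.57 (3 adjusted over the list alone), a call that ended without 6 arrays (all but rok against wt replicate 4 and rok-comK against comK replicate 2, adjusted p up to 0.196). In SPβ yoqM differed by -1.46 (SE 0.182, adjusted p = 0.00075) and yorX by -0.79 (2 of 153, 2 adjusted over the list alone), and the call of yorX ended without 4 arrays (replicates 2 and 3 of each comparison, adjusted p up to 0.109). In limma none passed, over all genes or adjusted over the list alone, of 10 genes of the published Rok-repressed operons, 15 of eps, 4 of poly-gamma-glutamate, 14 of purine and 9 of arginine synthesis (0 each at an unadjusted p under 0.05). The same held for 4 matrix protein, 20 regulator, 15 secreted enzyme and 14 early sporulation genes (1 each at that p), and 29 mother cell genes (2). It held for 32 other antibiotics and 35 forespore genes (4 each), 32 PBSX and 42 coat genes (5 each), and 38 skin and 54 ribosomal genes (6 each). Of 12 cannibalism toxin and 11 iron genes none passed over all genes (1 and 3 adjusted over the list alone, 3 and 4 at that p). The mother cell, forespore, coat and PBSX lists were called lower in rok against wt (medians -0.12, -0.23, -0.18 and -0.22, adjusted p = 0.00927, 2.14e-05, 0.00465 and 3.67e-06) and the iron list higher (0.47, adjusted p = 0.00927). With an estimated correlation their adjusted p were 0.913, 0.812, 0.913, 0.812 and 0.812. Without rok against wt replicate 3 the mother cell, forespore, coat and iron calls ended (medians 0.01, -0.09, 0.03 and 0.21), and without replicate 2 that of the coat list (-0.07). The subtilosin, SPβ, Rok-repressed operon, other antibiotics, matrix protein, eps, poly-gamma-glutamate, skin, regulator, ribosomal, secreted enzyme, early sporulation, purine, arginine and cannibalism lists were not called (adjusted p = 0.0879, 0.392, 0.584, 0.584, 0.726, 0.738, 0.584, 0.416, 0.392, 0.272, 0.6, 0.576, 0.898, 0.656 and 0.373).

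The nitrate reductase genes were higher in rok against wt than in rok-comK against comK. The subunit gene narG differed by 1.14 (SE 0.201), narH by 1.08 (SE 0.168, adjusted p = 0.00442), narJ by 0.9 and narI by 0.62, 4 of 20 in the anaerobic list (6 higher and 1 lower adjusted over the list alone). The calls of narG, narJ and narI ended without 2 arrays (rok-comK against comK replicates 2 and 4), 3 arrays (replicates 2, 3 and 4) and 7 arrays (all but rok-comK against comK replicate 1), with adjusted p up to 0.0565, 0.0858 and 0.202. The gene sucD differed by 1.09, 1 of 12 (1 adjusted over the list alone), and immA (ydcM) by 0.81, 1 of 20 in ICEBs1 (1 adjusted over the list alone). Their calls ended without 5 arrays (rok against wt replicate 2 and the 4 rok-comK arrays, adjusted p up to 0.0736) and 7 arrays (all but rok against wt replicate 4, up to 0.15). In general stress 6 of 28 were lower (18 adjusted over the list alone), among them ohrB by 1.1 (SE 0.212) and ydaD by 0.97 (SE 0.176). These 2 calls ended without 4 arrays (rok against wt replicate 2, rok-comK against comK replicates 2, 3 and 4, adjusted p up to 0.0799) and 1 array (rok-comK against comK replicate 4, -0.93, adjusted p = 0.0628). The anaerobic list was called higher (adjusted p = 0.000922) and the general stress list lower (6.62e-12), with adjusted p = 0.812 and 0.66 with an estimated correlation, and the tricarboxylic acid cycle and ICEBs1 lists were not called (adjusted p = 0.44 and 0.0602).

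Over all genes the difference passed for 121 of 3989, 104 higher in rok against wt and 17 lower, and for 59 with at least a 2-fold difference (54 and 5). The set test called 9 of 27 lists (4 higher, 5 lower), and with an estimated correlation 1, late competence. The slide numbers of the comparisons do not overlap in range, so effects of the slides and of the comparison cannot be told apart here. The count was 72 without a dye coefficient, and 71, 79 and 66 without rok-comK against comK replicates 2, 3 and 4.

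The effects of the rok label in the 2 comparisons overlapped. Of 3990 genes tested in both, 100 rose in both (13 expected, two-sided Fisher's exact test, p = 6.25e-74) and 22 fell in both (3.58 expected, p = 1.77e-12). The test takes genes as independent, which genes of 1 operon are not, and both sets of calls use the same spread per gene. These p-values may therefore be far too small. Risen in both were yorD, yxkC, yjcM, yknV and sunS, and fallen in both were bslA, yobB, yoqM, yoqL and bacC. The difference was not called for 118 of these 122 genes. Only oxdC (oxalate decarboxylase) and bglC (yckE) were called in opposite directions, at 0.44 and -0.96, and 0.43 and -0.48. The rok against wt call of oxdC ended without 2 arrays (rok against wt replicates 1 and 2, adjusted p up to 0.0987). Those of bglC ended without 6 (all but rok against wt replicate 1 and rok-comK against comK replicate 2) and 7 arrays (all but rok against wt replicate 1), with adjusted p up to 0.225 and 0.344. Across genes, which are not independent replicates, the fold changes had Pearson's r = 0.411 and Spearman's rho = 0.322, and r = 0.499 without the late competence list. The count risen in both was 59 without a dye coefficient, 65 on the authors' values, and 58 and 65 without rok-comK against comK replicates 2 and 4. The count fallen in both was 12 without rok against wt replicate 2, and 9, 10 and 9 without rok-comK against comK replicates 2, 3 and 4.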

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

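Tests of the rok probe and of the general stress list, and the test of the whole motility list, were chosen only after the result was seen, while the counts over other groupings of the arrays and the test of position were planned.

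The rok gene encodes the repressor under study, and its probe was brighter in both strains that carry the rok label. An exchange of strains or dyes on some of the arrays is argued against by the neo marker probe, whose lowest log2 ratio over the 8 arrays was 5.05. That probe set the reading of the dyes and cannot test an exchange on all 8, which the published Rok-repressed operons argue against (lowest median per array 0.82) if the rok label means a loss of Rok, which the labels do not state. Transcription running on from an inserted marker may have raised neighbouring genes, but the highest log2 change of the 10 genes beside rok was 0.55. These 10 do not cover every gene near it. The gene yknV (BSU14330, with rok at BSU14240) is not among them and rose by 2.31 and 2.34 in the 2 comparisons. The test therefore speaks only for the 10 genes. How rok was changed in these strains stays open, and no biological explanation was tested.

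Flagellar genes rose beside the comF operon. A rise of the whole motility list is argued against by a median log2 change of -0.07 over its 38 members away from raised late competence genes. Of these 38, 0 were called up in limma, against 8 of 10 near ones. Only 5 of the 8 had a called difference. The others, flgB, flgC and fliE, do not lie beside comF, and flgB was also called up in rok-comK against comK (0.58). Of 38 genes outside the late competence list with a rise of at least 2-fold and a called positive difference, 17 lay within 10 genes of a raised late competence gene (median over 4105 circular shifts of the gene order 1, highest 17, permutation p = 0.00438). The test takes no account of strand or direction, and beyond comFA the genes yvyE (1.13) and tagV (0.99) rose past fakBA (0.23) and degU (-0.11), which were not called, so what links position and rise stays open. Of 39 genes that rose at least 2-fold in rok-comK against comK, 0 lay in such a window. This lies close to the median of 1 that the shifts gave for the 38 genes. The windows were also set by rises in rok against wt, so this 0 says little.

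General stress genes, which SigB activates, had a median of -0.2 in rok against wt and 0.37 in rok-comK against comK. No single array carried the difference, whose median stayed at -0.368 or lower without each of the 8 arrays. A trend of the ratio with intensity is argued against by medians of -0.491 or lower under median centring and loess within each grid. Genes of the list varying together from colony to colony cannot be told apart from it, since with an estimated correlation the adjusted p was 0.66. Per-array medians were -0.04, -0.24, -0.13 and -0.4 in rok against wt, and 0.04, 0.64, 0.1 and 0.37 in rok-comK against comK, so they did not overlap, while that explanation was taken to need an overlap.

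Other groupings of the arrays were counted. In rok against wt the real orientation gave 518 genes and the highest other of 8 sign assignments 0, and in rok-comK against comK 237 and 0. In each, 1 assignment reached the real count, the real one, and 8 are too few for a share under 0.05. For the difference 1 of 34 splits, the real one, gave as many as 121 genes, and the highest other gave 1. That is the smallest share this count can reach, and it assumes independent arrays that are exchangeable between the comparisons. Some arrays may share a culture, and the slide numbers of the comparisons do not overlap in range, so the count cannot exclude chance.

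Groups of 4 arrays were examined for 1 array far from the other 3, which chance gives in about 1 in 20 for independent normal values. The ratios used include the dye effect and many groups share arrays, so that rate is only a rough guide. In 17 of 348 groups 1 array lay that far out. In rok against wt these were bslA at -2.15 on replicate 3 (others -3.33 to -3.15), ctc at -0.06 on replicate 4, rsbW at -0.63 on replicate 3, skfA at -1.55 on replicate 1, carA at 1.18 on replicate 2, xynA at 0.08 on replicate 1, spmB at -0.63 on replicate 3 and yoqJ at -1.28 on replicate 2. List medians did so for regulators at -0.04 and mother cell genes at 0.23 on replicate 1, and PBSX at -0.1 on replicate 2. In rok-comK against comK they were comGF at -2.22 on replicate 4 (others 0.08 to 0.38), dprA at 0.53 on replicate 2, ydaD at 0.17 on replicate 1, csbA at 0.43 on replicate 2, bglC at -0.22 on replicate 1, and the ICEBs1 median at 0.29 on replicate 3.

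The 48 differences below are rok against wt minus rok-comK against comK, each called by the test of the difference. In competence they were comK 1.44, comGF 5.65, comGC 4.52, comGD 4.43, comGB 4.42, comFA 4.05, nucA 3.98, comFB 3.52, nin 3.3, comEB 3.13, dprA 2.85 and rapH 2.75. In motility they were flgN 3.8, flgL 3.78, flgM 3.69, flgK 3.09, fliW 2.21 and csrA 0.9. In respiration and the tricarboxylic acid cycle they were narG 1.14, narH 1.08, narJ 0.9, narI 0.62 and sucD 1.09. In general stress they were ohrB -1.1, ydaD -0.97, lyxE -0.77 and ydaG -0.77. In peptides and mobile elements they were albD 0.57, yoqM -1.46, yorX -0.79 and immA 0.81. In other metabolism they were oxdC 1.4, gntP 0.97, bglC 0.91, gntK 0.68, hutH -1.05, hutU -1.04, mdxG 0.92, mdxJ 0.92, mdxL 0.89, mdxK 0.85, mdxF 0.83 and mdxD 0.79. The rest were glcR 2.88, engD 2.56, efp 2.32, papA 2.08 and walI -1.06. The calls that ended without 1 array are given with the genes in the report and among the other observations, and those of lyxE and ydaG ended without 6 arrays each (all but rok against wt replicate 4 and rok-comK against comK replicate 1, and all but replicate 1 of each comparison, adjusted p up to 0.15 and 0.156), and that of bglC without 3 (rok against wt replicate 2, rok-comK against comK replicates 1 and 2, up to 0.0665).

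Probes for resistance markers enter no fit, though that of neo set the reading of the dyes. Only some of them were brighter in the rok-labelled strain on all arrays of a comparison: neo by 5.57 in rok against wt and by 6.17 in rok-comK against comK, and in the latter tet by 2.5 and kan by 1.32. In rok against wt tet was brighter as well, but above background in wt on only 1 of 4 arrays, and in comK it was on 2 of 4, so the size of its ratios is uncertain. The size for neo is uncertain too, since its median net intensity in the rok-labelled strains was over 40000 and it was above background in wt on 3 of 4 arrays.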

How the results depend on the processing

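The filters on genes never above background (519, 237 and 122 genes for rok against wt, rok-comK against comK and the difference) and on spots over 40000 (454, 220 and 109) were tests chosen after seeing the data. The late competence list kept its calls in rok against wt and in the difference under all 24 settings run, with medians of 1.05 to 2.86 and 0.986 to 2.8, the lowest of each under the filter on spots over 40000. bslA kept its calls in both comparisons under all 23 settings, at -3.2 to -2.39 and -2.8 to -1.99.

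Counts moved more, and the cause was not tested unless stated. Without a dye coefficient 240, 96 and 72 genes were called, with 59 risen and 10 fallen in both. Separate fits, which share neither the spread nor the dye coefficient, gave 186 and 663 genes, with 10 fallen in both. With a dye coefficient per comparison and a shared spread the counts were 487 and 183. With the arrays scaled to 1 spread in the shared fit they were 413 and 444. Which comparison has more calls thus depends on pooling the spread and on scaling the arrays. The shared fit gives both comparisons 1 spread per gene. The median absolute difference of duplicate spots was 0.081 to 0.104 per array in rok against wt and 0.051 to 0.07 in rok-comK against comK. A 2-fold minimum left 111, 47 and 59 genes by construction, with 32 risen and 4 fallen in both. Duplicate spots kept apart gave 187 differences and 56 fallen in both. On the authors' values 106 genes were called in rok-comK against comK, with 65 risen and 14 fallen in both. In that comparison plain background subtraction gave 136, median centring 122 and scaling to 1 spread 444. Under median centring 83 of 86 called differences were positive (96.5%, against 86.0%). A replicate block left 82 differences.

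Leaving out 1 array gave 280 to 542 genes in rok against wt, 82 to 331 in rok-comK against comK and 66 to 153 differences. It gave 58 to 106 genes risen and 9 to 31 fallen in both. Lists called numbered 9 to 17, 10 to 14 and 6 to 12. With an estimated correlation they were 1, 0 (5 at an unadjusted p under 0.05) and 1, and by fry 7, 5 and 1.

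Reversals were 3, and their cause was not tested. The ribosomal list in rok-comK against comK was called up under median centring (median 0.151), the difference of yorD was -0.812 with scaled arrays, and yozH in rok against wt, above background in neither strain, was -1.14 on the authors' values against 0.78.

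Keeping spots the scanner software marked could not be run, since they hold no values. Low signal over background limits dim genes, and spots over 40000 limit bright ones.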

Other observations

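Genes in this part were chosen after their values were seen, and no tests beyond those given above were made of them. The 38 genes in the test of position include efp, papA, engD, glcR and the mdx genes named here. Of these, only glcR lay within 10 genes of a raised late competence gene.

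Genes outside the lists differed as well. The translation factor gene efp and its neighbour papA (yqhT, a peptidase) rose in rok against wt by 2.2 (SE 0.087) and 1.93 (SE 0.082), the GTPase gene engD (yyaF) by 2.36 (SE 0.113) and the sugar regulator gene glcR by 2.72 (SE 0.107). In rok-comK against comK these values were -0.13, -0.15, -0.2 and -0.16, none of them called. Genes for maltodextrin use rose by 1.08 (mdxF) to 1.21 (mdxJ) in rok against wt, with mdxD, mdxG, mdxK and mdxL between. Their called differences ended on leaving out 1 array, except that of mdxG (0.92, adjusted p = 0.00782). Those of mdxD, mdxF and mdxJ ended without rok against wt replicate 3 or rok-comK against comK replicate 1, 3 or 4 (adjusted p up to 0.0763, 0.0892 and 0.0955), and those of mdxK and mdxL without rok against wt replicate 2 or the same 3 rok-comK arrays (up to 0.0694 and 0.0728).

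The histidine degradation genes hutH and hutU rose in rok-comK against comK by 1.19 (SE 0.13) and 1.16 (SE 0.101), as did walI (yycI), which restrains an essential sensor kinase, by 1.05 (SE 0.137). In rok against wt their values were 0.15, 0.12 and -0.01, not called. The gluconate genes gntP and gntK fell by 1.23 (SE 0.121) and 1.24 (SE 0.103) in rok-comK against comK, and gntK also in rok against wt, by 0.56. The difference of hutH was not called without rok-comK against comK replicate 2 (-1.01, adjusted p = 0.0561), nor that of walI without its replicates 2 and 4 (-1.08 to -0.99, up to 0.0628). That of gntK ended without 6 arrays (all but rok against wt replicate 1 and rok-comK against comK replicate 3, up to 0.15).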
